A study of Homo sapiens with 8 samples.

How the data were processed

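Gene expression was measured on Affymetrix arrays from total RNA, with biotin as the label. The cells were T47D, a human breast cancer cell line of luminal type with oestrogen and progesterone receptors. The 8 arrays cover 4 lines with 2 arrays each. The lines WT and shEGFP were the controls, the latter with a hairpin RNA against EGFP, and the lines sh2608 and sh3293 carried hairpin RNAs (shRNA) against ERBB3. Per the labels' protocols, hairpins were brought in by lentivirus and infected cells were selected with puromycin, and this protocol is given alike for all samples, so it does not settle whether WT cells were infected or selected. The labels do not say that the arrays of a line came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

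The deposited table holds 1 intensity per probe set and array on a linear scale. Per the submitters' processing notes PLIER made these values; its version and settings are not given in the sources used here. Array medians lay between 103.07 and 103.6 and every array had the same highest intensity of 16271, so the values had been brought to nearly the same distribution before deposit, and no further normalization was applied. The lowest intensity was 0.95. Such a shared distribution hides any change in total RNA, and a shift of many probe sets in one direction moves others the opposite way.

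Of 33297 probe sets, the platform annotation gives exactly 1 gene symbol for 19460 and several for 1754, while 12083 are not listed there and stay unnamed. Symbols were checked through their Entrez identifiers, of which 99.8% were found in the reference gene table, and no coordinates were used. A gene was represented by its probe set with exactly 1 symbol or, among several such probe sets, by the one with the highest mean over the 8 arrays. This gave 18417 genes, 769 of them with more than 1 probe set. Another probe set had identical values on all arrays for 1242 probe sets.

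Tests were run on log2(intensity + 16), a scale that understates the fold change of dim genes. Models were fitted in R 4.3.3 with limma 3.58.1 and statmod 1.5.0 (lmFit, eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05; genes past it are termed called, and rose, fell, higher and lower are used of these. ERBB3 shRNA versus control set 4 arrays against 4 with the line as a random block, whose arrays had a correlation of 0.198. Each hairpin line against the mean of both controls, sh3293 against sh2608, and shEGFP against WT were contrasts in a model with a mean per line, where all 8 arrays share 1 estimate of the spread. Standard errors (SE) are those of the model. The number of arrays limits the precision.

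Before the data were examined, the tests, the rule for naming genes, most alternative analyses and 23 gene lists were fixed. The lists cover ERBB receptors and ligands, other receptor tyrosine kinases and adaptors, FOXO targets, ERK pathway output, oestrogen response, luminal markers, basal and myoepithelial markers, mesenchymal and fibroblast markers, mammary secretory differentiation, mitosis, DNA replication, p53 targets, BCL2 family, interferon response, NF-kB, unfolded protein and ATF4 response, cholesterol synthesis, fatty acid synthesis, hypoxia and glycolysis, lysosome and autophagy, ribosomal proteins, haematopoietic markers and endothelial markers. Of 470 entries, 426 were measured by a probe set with 1 symbol, and 3 symbols were updated. Each list was tested with camera in the mean-per-line model at a preset correlation between genes of 0.01, and again with an estimated correlation, with adjustment over the 23 lists of a comparison. Members were counted by the test of each gene, which in ERBB3 shRNA versus control keeps the line as a block. Camera does not, so its p-values leave out the spread between lines.

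The rule names ERBB3; for ERBB3 shRNA versus control the 12 highest and 12 lowest changes among called genes whose 4 hairpin arrays do not overlap the 4 control arrays; for each other comparison the 5 highest and 5 lowest called genes; and per list up to 4 called members with the largest change or, with none called, the 2 with the smallest p. Had fewer than 5 genes passed in the first comparison, genes called in both hairpin lines would have taken their place. Members of the ERBB list may always be named.

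The scripts were tested on simulated arrays with 200 changed probe sets among 33297. For ERBB3 shRNA versus control, 46% of those changed by 0.5 on the log2 scale were recovered, 94% of those changed by 1 and 100% of those changed by 2 or 4, and 20 of 190 calls were false (10.5%), above the nominal share. For sh2608 versus control, 42% of the changes of 0.5 and 98% of those of 1 were recovered, with 15 of 185 calls false. For sh3293 versus control these shares were 46% and 94%, with 11 of 181 calls false. With random differences between lines at the estimated correlation, 96 of 270 calls were false for sh2608 and 111 of 280 for sh3293. This is because a single line does not separate its hairpin from other differences between lines. These arrays gave 23 calls for shEGFP versus WT and 4 for sh3293 versus sh2608, against 894 and 852 in the data. Real lines thus differed more than simulated ones. The shares of false calls given here, the 10.5% included, may therefore be too low for these data. All 5 simulated lists of 25 genes raised by 0.3 were called, and 0 of 20 unchanged lists by camera. Simulated genes varied independently, while the estimated correlation within the real lists reached 0.364. The 0 therefore does not give the rate of false list calls in these data.

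Alternatives covered the pseudocount, quantile normalization, median centring, leaving out dim probe sets, averaging the probe sets of a gene, the variance model, a 2-fold minimum, the replicate number as a block, other models and control groups, another test of lists, and leaving out each array in turn. Testing only probe sets with 1 gene symbol, keeping identical probe sets once, testing lists with WT as the only control and leaving ERBB3 out of its lists were chosen after seeing the data.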

Results

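Expression was compared between 4 lines of T47D cells to find what changes when ERBB3 is lowered by RNA interference. WT, shEGFP, sh2608 and sh3293 were each measured on 2 arrays. Across probe sets on the log2 scale, the arrays of a line correlated at 0.989 to 0.991, and no array correlated above 0.988 with an array of another line.

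ERBB3, a receptor of neuregulins that signals with other ERBB receptors, was measured by 1 probe set (7956120). Its intensity was 1710 ± 51.7 (SD, n = 2) in WT and 1629 ± 8.51 (SD, n = 2) in shEGFP, against 474 ± 16.9 (SD, n = 2) in sh2608 and 435 ± 10.0 (SD, n = 2) in sh3293. On the scale of the tests, log2(intensity + 16), the difference from the controls was a 3.44-fold decrease in sh2608 and a 3.74-fold decrease in sh3293. In ERBB3 shRNA versus control ERBB3 fell by 1.84 on the log2 scale (SE 0.0811, limma adjusted p = 1.4e-09), a 3.59-fold decrease on that scale seen in 4 of 4 hairpin arrays. An exact two-sided permutation test of 4 against 4 arrays gave p = 0.0286, which treats the 8 arrays as exchangeable; with whole lines as units only 3 groupings exist. ERBB3 differed between sh3293 and sh2608 by -0.12 (95% interval -0.28 to 0.04, limma adjusted p = 0.497) and between shEGFP and WT by -0.07 (limma adjusted p = 0.717).

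**Figure D1:**
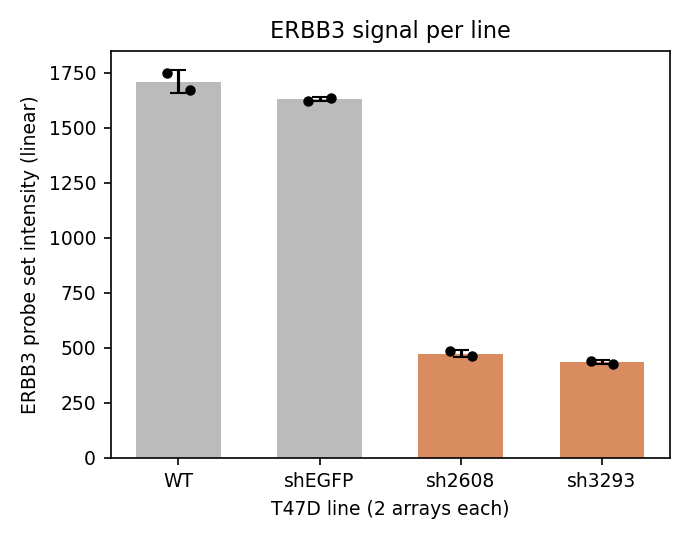
Intensity of the ERBB3 probe set on a linear scale (vertical axis) in the 4 T47D lines (horizontal axis), with bars for means, error bars for SD and points for the 2 arrays of a line. The sh2608 and sh3293 arrays lie between 427.8 and 485.9, and the control arrays between 1623 and 1747.

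ERBB3 shRNA versus control asked which genes changed across both hairpin lines. The largest rise was that of LMO3, a LIM-domain protein of transcription complexes, at 2.10 on the log2 scale (SE 0.220, limma adjusted p = 8.46e-05), and its relative LMO4 rose by 1.49 (SE 0.104). The semaphorin SEMA3D rose by 1.75, the growth factor TGFB2 by 1.71, the vasodilator peptide ADM by 1.64 and the matrix protein NPNT by 1.53. ADM was also lower in shEGFP than in WT, a call that was lost without some single arrays. Its rise is therefore smaller against WT alone than against the mean of both controls. PGM2L1, an enzyme of sugar phosphates, rose by 1.89, the vesicle transport protein SYTL2 by 1.63, the cell surface antigen PSCA by 1.62, BRINP3 by 1.61, the catenin CTNND2 by 1.52 and the protease PRSS23 by 1.48. After ERBB3, the largest falls were those of the secreted glycoprotein AZGP1 at -1.57 (SE 0.142, limma adjusted p = 2.56e-05), the secreted protein OLFML3 at -1.55 and the semaphorin receptor PLXND1 at -1.29.

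NKAIN1 fell by 1.24, the phospholipase PLCE1 by 1.19, CA8 by 1.17, the glutamate receptor subunit GRIK4 by 1.14 and the potassium channel KCNMA1 by 1.14. ETNK2, an ethanolamine kinase, fell by 1.13, the LIM-domain protein FHL2 by 1.12 and the peroxisomal oxidase ACOX2 by 1.04. Of 33297 probe sets 278 were higher and 200 lower, and of 18417 genes 239 were higher and 151 lower, 56 and 16 of these by at least 2-fold. All 390 called genes had hairpin arrays that did not overlap the control arrays, as did 2535 genes in all (13.8%). Chance gives 2.86% if all 8 arrays are exchangeable, which arrays of a line are not, and the other groupings of whole lines gave 3.81% (WT and sh2608 against the rest) and 6.99% (WT and sh3293 against the rest). The total of 478 probe sets became 317 without WT replicate 2, 269 without shEGFP replicate 1, 274 without sh3293 replicate 1 and 310 without sh3293 replicate 2. KCNMA1 lost its call without shEGFP replicate 1 or 2 or sh3293 replicate 1 or 2 (limma adjusted p from 0.0527 to 0.0654), and PLCE1 without sh3293 replicate 1 (limma adjusted p = 0.0555).

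Of 29 measured interferon response genes 13 rose, 16 did not pass and 0 fell in limma, with 0 lower at an unadjusted p under 0.05 too, and 20 rose when adjusted over the list alone. The median change was 0.58 (camera adjusted p = 6.96e-19, adjusted p = 0.0545 with an estimated correlation). IFIT1, which binds viral RNA, rose by 1.47 (SE 0.206), IFI6 by 1.41 (SE 0.145), OAS2, an enzyme activated by double-stranded RNA, by 1.20 (SE 0.181) and the antiviral GTPase MX1 by 1.18 (SE 0.124). In shEGFP versus WT the median of this list was -0.20.

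Of 27 measured oestrogen response genes 8 fell, 19 did not pass and 0 rose in limma, with 1 higher at an unadjusted p under 0.05, and 17 fell and 1 rose when adjusted over the list alone. The median was -0.35 (camera adjusted p = 6.18e-12, adjusted p = 0.286 with an estimated correlation). The progesterone receptor PGR fell by 0.64 (SE 0.0698), GREB1 by 0.78 (SE 0.0933) and the secreted protein OLFM1 by 0.81 (SE 0.0875). In shEGFP versus WT this list was also lower, with a median of -0.25 (adjusted p = 0.294 with an estimated correlation). Its mean differed in sh2608 and sh3293 by -0.43 and -0.47 from WT, and by -0.16 and -0.20 from shEGFP.

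Mitosis and DNA replication genes were lower as lists, while no single member passed limma's test. These tests are not alike. Camera used the model with a mean per line, where the spread between lines does not enter, and single members the model with the line as a block. Mitosis had a median of -0.17 over 25 members (camera adjusted p = 7.43e-09, adjusted p = 0.286 with an estimated correlation), with 10 lower and 0 higher at an unadjusted p under 0.05 and 3 lower when adjusted over the list alone. AURKA, a kinase of spindle assembly, was at -0.41 (limma adjusted p = 0.0734) and TPX2, its activator, at -0.26 (limma adjusted p = 0.0933). DNA replication had a median of -0.12 over 24 members (camera adjusted p = 4.92e-05, adjusted p = 0.288 with an estimated correlation), with 6 lower and 0 higher at an unadjusted p under 0.05 and 0 past limma's test when adjusted over the list alone. In shEGFP versus WT the mitosis median was 0.13 and that of DNA replication -0.16. The mitosis mean differed in sh2608 and sh3293 by -0.04 and -0.16 from WT, and by -0.20 and -0.32 from shEGFP. For DNA replication these values were -0.21 and -0.18 from WT, and -0.07 and -0.04 from shEGFP, and with shEGFP as the only control DNA replication lost its call (camera adjusted p = 0.133).

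Basal and myoepithelial markers had a median of 0.33 over 14 members (camera adjusted p = 0.0407, adjusted p = 0.286 with an estimated correlation). The cadherin CDH3 rose by 0.75 (SE 0.0915) and the integrin ITGA6 fell by 0.43 (SE 0.102), and 2 rose and 3 fell when adjusted over the list alone. The list lost its call without WT replicate 1 (camera adjusted p = 0.0617), sh3293 replicate 1 (0.0595) or sh3293 replicate 2 (0.0542) and with shEGFP as the only control (0.142), and ITGA6 lost its own without any 1 of the 7 arrays other than sh3293 replicate 1 (limma adjusted p from 0.0780 to 0.117).

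The other 18 lists did not pass camera (adjusted p from 0.0680 to 0.996), and some of their members changed. Among other receptor tyrosine kinases and adaptors, MET, the receptor of hepatocyte growth factor, rose by 0.86 (SE 0.139) and 2 of 20 members were called. Of 18 ERBB receptors and ligands 1 was called, ERBB3 itself, while EGFR was at -0.49 (limma adjusted p = 0.120), ERBB2 at 0.27 (limma adjusted p = 0.353) and ERBB4 at 0.19 (limma adjusted p = 0.777). Of 22 FOXO targets 2 rose and 1 fell, with the cyclin CCNG2 at 0.95 (SE 0.100) and ERBB3 as the one that fell. Of 22 genes of ERK pathway output 1 rose and 3 fell, with the immediate early gene IER3 at -0.97 (SE 0.187) and the phosphatase DUSP5 at -0.62 (SE 0.110). The mean of the ERK list differed in sh2608 and sh3293 by -0.20 and -0.21 from WT, but by 0.08 and 0.07 from shEGFP. Of 20 luminal markers 1 rose, the tight junction protein CLDN4 by 0.45, and 1 fell. Of 21 mesenchymal and fibroblast markers 1 rose and 1 fell, the transcription factor TWIST1 by 0.89.

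Of 15 genes of mammary secretory differentiation 1 fell, the prolactin receptor PRLR by 0.81 (SE 0.109). In the list of the unfolded protein and ATF4 response the folate enzyme MTHFD2 fell by 0.40 and the amino acid transporter subunit SLC3A2 by 0.34, 2 of 20. SC5D, an enzyme of cholesterol synthesis, was the 1 of 15 that rose in its list, by 0.51. Of 19 genes of hypoxia and glycolysis ADM rose and 1 fell, and of 15 genes of lysosome and autophagy 2 fell. Median and mean differed in sign for ERK pathway output (0.02 and -0.07, camera direction down), hypoxia and glycolysis (-0.10 and 0.03, down), other receptor tyrosine kinases (-0.01 and 0.04, up) and the unfolded protein list (0.00857 and -0.0033, down).

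Called members of these lists not named above were GAB1, TNFSF10, IER2, MYC, XBP1, LUM, PFKFB3, WIPI1 and CTSD, and with MAPT of the oestrogen response list each lost its call when 1 of at least 2 arrays was left out (limma adjusted p up to 0.133, reached by MAPT without sh3293 replicate 1). The 9 lists with 0 members called by limma were mitosis, DNA replication, p53 targets, BCL2 family, NF-kB, fatty acid synthesis, ribosomal proteins, haematopoietic markers and endothelial markers. Their 149 members included 11 higher and 23 lower at an unadjusted p under 0.05. The median of haematopoietic markers was -0.08 and that of endothelial markers 0.13.

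**Figure D2:**
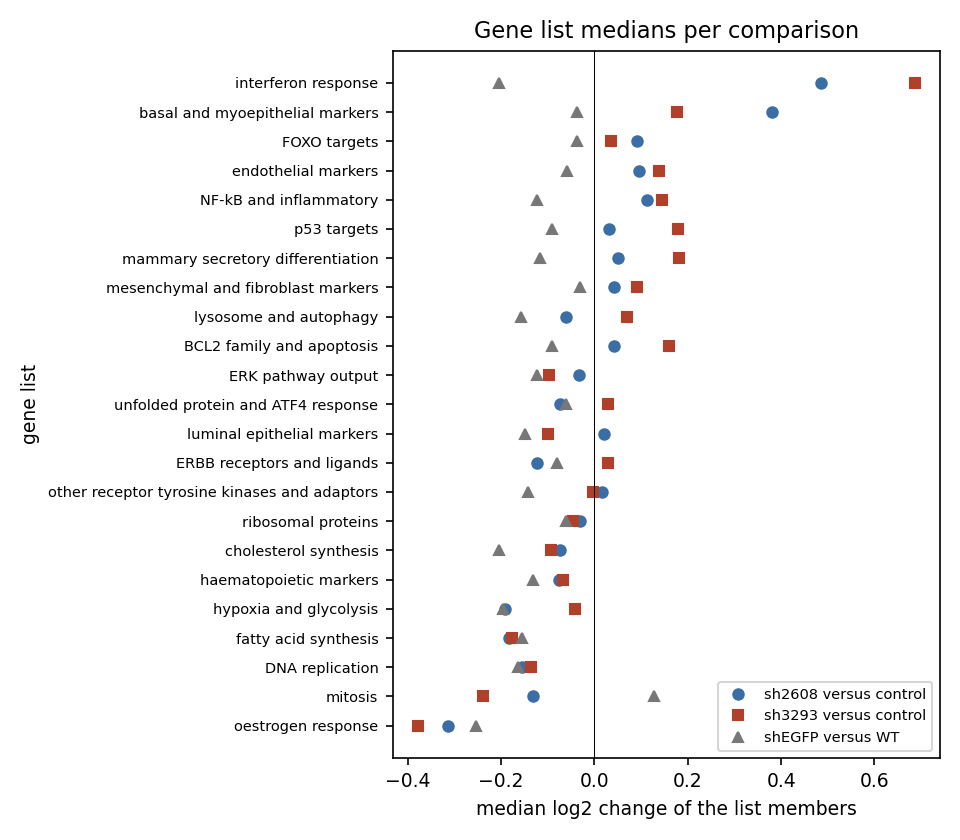
Median log2 change of the members of each gene list (horizontal axis) for each list (vertical axis, ordered by the median in ERBB3 shRNA versus control), with circles for sh2608 versus control, squares for sh3293 versus control and triangles for shEGFP versus WT. Interferon response lies at 0.49 and 0.69 in the hairpin lines and at -0.20 in shEGFP, and oestrogen response at -0.31, -0.38 and -0.25. The median over all genes was -0.02 in sh2608, -0.01 in sh3293 and -0.06 in shEGFP versus WT.

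In sh2608 versus control the largest rise was that of CCL2, a chemokine that attracts monocytes, at 3.26 on the log2 scale (SE 0.147, limma adjusted p = 2.22e-08), or 9.61-fold on that scale. LMO3 rose by 2.47, TGFB2 by 2.34, the collagen gene COL3A1 by 2.26 (SE 0.174) and PSCA by 2.14. ERBB3 fell by 1.78, OLFML3 by 1.73, CA8 by 1.59, AZGP1 by 1.57 and PLXND1 by 1.45. Of 33297 probe sets 768 were higher and 598 lower, and of genes 568 were higher and 472 lower, 79 and 16 of them by at least 2-fold.

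Of the 23 lists 8 were called in sh2608. Of 29 interferon response genes 16 rose, with IFIT1 at 1.88 and IFI6 at 1.72 (camera adjusted p = 1.09e-19, adjusted p = 0.0504 with an estimated correlation). Of 27 oestrogen response genes 13 fell and 2 rose, with the transcription factor MYB at -0.93 and RERG at -0.74 (camera adjusted p = 1.19e-11, adjusted p = 0.204 with an estimated correlation). Of 14 basal and myoepithelial markers 4 rose and 1 fell, with smooth muscle actin ACTA2 at 0.89 (camera adjusted p = 0.00247, adjusted p = 0.204 with an estimated correlation). Of 21 mesenchymal and fibroblast markers 3 rose, COL3A1, the proteoglycan LUM by 1.34 and fibronectin FN1 by 0.88, and 1 fell (camera adjusted p = 0.0336, adjusted p = 0.204 with an estimated correlation).

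Mitosis was lower in sh2608 with 4 of 25 members called (camera adjusted p = 0.000162, adjusted p = 0.425 with an estimated correlation). Its list mean differed by -0.20 from shEGFP and by -0.04 from WT, and with WT as the only control, tried after seeing the data, it was not called (camera adjusted p = 0.362). DNA replication was lower with 1 of 24 (camera adjusted p = 8.49e-06, adjusted p = 0.204 with an estimated correlation). The NF-kB list was higher with CCL2 as the 1 called of 16 (camera adjusted p = 0.0336, adjusted p = 0.204 with an estimated correlation). Its median was 0.11 against a mean of 0.295, and it was not tested without CCL2. The ERBB list, which holds the hairpin's target ERBB3 among the 3 of 18 that fell, while 1 rose, was called lower (camera adjusted p = 0.0336, adjusted p = 0.425 with an estimated correlation) but not once ERBB3 was left out (camera adjusted p = 0.243). FOXO targets, which also hold ERBB3 and were not called with it, were called higher once it was left out (camera adjusted p = 0.0171, adjusted p = 0.374 with an estimated correlation); leaving it out was chosen after seeing the data. ERBB2, the signalling partner of ERBB3, was at 0.50 (SE 0.0809, limma adjusted p = 0.00291, or 0.101 without sh2608 replicate 1). Outside the called lists EGLN3, an oxygen-dependent hydroxylase, rose by 1.84, the epithelial transcription factor ELF3 by 0.83 and PRLR fell by 0.92. Median and mean differed in sign for the mammary secretory and hypoxia lists, neither of them called.

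The total of 1366 probe sets in sh2608 versus control became 775 and 806 without WT replicates 1 and 2, 674 and 749 without shEGFP replicates 1 and 2, and 421 and 309 without sh2608 replicates 1 and 2. Lost list calls were those of the ERBB list without WT replicate 2 (camera adjusted p = 0.0501) or sh2608 replicate 2 (0.142), the mesenchymal list without WT replicate 1 (0.0655) or sh2608 replicate 1 (0.160), and NF-kB without WT replicate 1 (0.0622), shEGFP replicate 1 (0.0965) or sh2608 replicate 2 (0.0682). With shEGFP as the only control the ERBB (camera adjusted p = 0.104), mesenchymal (0.0704) and NF-kB (0.0704) lists lost theirs as well.

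In sh3293 versus control the largest rise was that of PGM2L1 at 2.40 on the log2 scale (SE 0.188, limma adjusted p = 5.56e-06), followed by SEMA3D at 2.18, SYTL2 at 1.78, LMO3 at 1.74 and AKR1C3 at 1.73. AKR1C3 encodes an aldo-keto reductase of steroid metabolism, and its probes may also bind transcripts of close paralogs. It was also lower in shEGFP than in WT, so its rise is smaller against WT alone than against the mean of both controls. After ERBB3 at -1.90, PLCE1 fell by 1.79, the secreted glycoprotein STC2 by 1.67 (SE 0.0567, limma adjusted p = 2.77e-09), the carboxypeptidase CPA4 by 1.66 and AZGP1 by 1.57. Of 33297 probe sets 1555 were higher and 1642 lower, and of genes 1092 were higher and 1204 lower, 71 and 37 of them by at least 2-fold.

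Of the 23 lists 5 were called in sh3293. Of 29 interferon response genes 17 rose, with IFI6 at 1.10, OAS1 at 1.08 and IRF9, a transcription factor of the interferon pathway, at 1.08 (camera adjusted p = 1.19e-13, adjusted p = 0.100 with an estimated correlation). Of 27 oestrogen response genes 16 fell and 3 rose, with OLFM1 at -0.93 and the trefoil factor TFF3 at -0.80 (camera adjusted p = 1.99e-09, adjusted p = 0.370 with an estimated correlation). Of 25 mitosis genes 10 fell, with the kinetochore protein CENPF at -0.56 and AURKA at -0.53 (camera adjusted p = 1.99e-09, adjusted p = 0.370 with an estimated correlation). DNA replication was lower with 2 of 24 called (camera adjusted p = 0.0110, adjusted p = 0.686 with an estimated correlation). Of 18 p53 targets 3 rose and 1 fell, with the cell cycle inhibitor CDKN1A at 0.65 and DDB2 at 0.49 (camera adjusted p = 0.0435, adjusted p = 0.547 with an estimated correlation).

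Outside the called lists, the oestrogen receptor ESR1 fell by 0.81 in sh3293 (SE 0.0834), the ERBB ligand EGF rose by 0.98 (SE 0.125), the feedback inhibitor ERRFI1 rose by 0.70 and LRIG1 fell by 0.60. IER3 fell by 1.42 and DUSP4 by 1.05, both of ERK pathway output. DUSP4 was also lower in shEGFP than in WT, and the mean of this list was not below that of shEGFP in sh3293 (0.07 from shEGFP, -0.21 from WT). EGFR was at -0.63 (limma adjusted p = 0.00683, or 0.0550 without sh3293 replicate 1). Median and mean differed in sign for the ERBB, other receptor kinase, cholesterol and hypoxia lists, none of them called.

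The total of 3197 probe sets in sh3293 versus control became 2102 without WT replicate 1, 1879 and 2025 without shEGFP replicates 1 and 2, and 1489 without sh3293 replicate 2. The DNA replication list lost its call without sh3293 replicate 2 (camera adjusted p = 0.179), and p53 targets without WT replicate 2 (0.0860), shEGFP replicate 2 (0.0612) or sh3293 replicate 1 (0.197). DNA replication also lost it with shEGFP as the only control (0.595) and by fry (0.0529), and p53 targets with shEGFP (0.0840) or WT (0.0605, chosen after seeing the data) as the only control and with the replicate number as a block (0.0562).

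Calls shared by the hairpin lines were counted per direction. Of 18417 genes 331 were higher and 240 lower in both, and 25 went opposite ways. Of the 390 genes called in ERBB3 shRNA versus control, 376 were among the 571 shared in direction. Independent lists of these sizes would share 33.7 higher and 30.9 lower genes, and 100 simulations of unchanged groups against the shared controls gave 0 shared calls in limma. With random differences between lines added, at the estimated correlation of arrays of a line and after seeing the data, 100 simulations gave 0.31 on average and at most 2. Arrays simulated at this setting gave 23 calls for shEGFP versus WT and 4 for sh3293 versus sh2608, where the data gave 894 and 852. Real lines thus differed more than simulated ones, so neither simulation decides how much sharing such differences alone would give. Among probe sets 700 were shared in direction.

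Across genes, which are not independent replicates, the changes in the hairpin lines correlated at 0.538, against 0.336 on average in the simulations (0.321 to 0.357). Their covariance was 0.0382 against a simulated 0.00783, a difference of 0.0304, or against 0.0116 with random differences between lines, a difference of 0.0266. Since lines differed less in these simulations than in the data, the simulated values may be too low. With separate controls, sh2608 versus WT and sh3293 versus shEGFP shared 181 higher and 127 lower genes, against 28.8 and 27.9 for independent lists, with 69 genes called in opposite directions, a correlation of 0.232 and a covariance of 0.0204. In the opposite assignment of controls 212 higher and 135 lower genes were shared, against 17.4 and 13.4, with 12 genes in opposite directions, a correlation of 0.365 and a covariance of 0.0293. The 700 probe sets became 412 and 421 without WT replicates 1 and 2, 373 and 389 without shEGFP replicates 1 and 2, and 262 and 199 without sh2608 replicates 1 and 2.

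**Figure D3:**
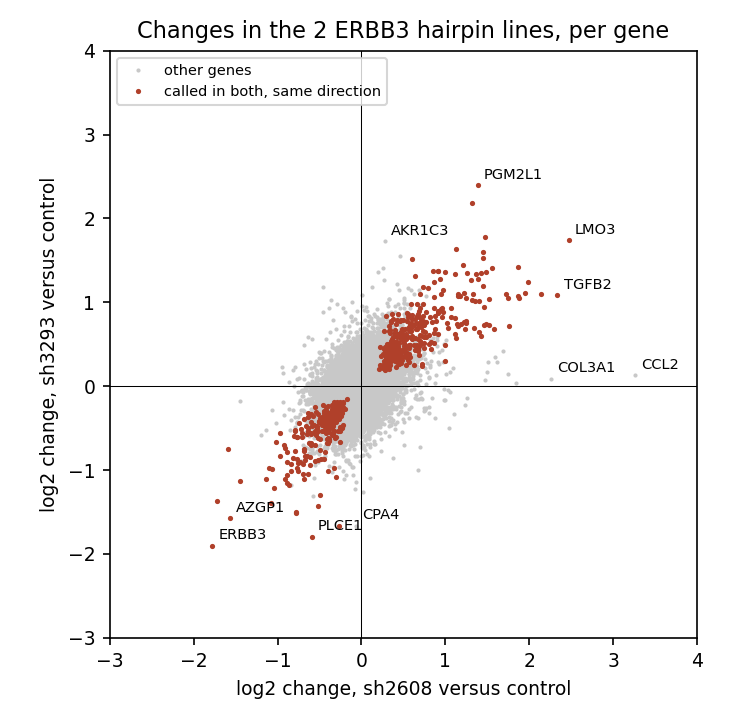
Log2 change of each of 18417 genes in sh2608 versus control (horizontal axis) and sh3293 versus control (vertical axis), with red points for the 571 genes called in both lines in the same direction and grey points for other genes. ERBB3 lies at -1.78 and -1.90, and CCL2 at 3.26 and 0.13.

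The comparison of sh3293 with sh2608 tested the difference between the hairpin lines itself. CCL2 was lower in sh3293, at -3.13 on the log2 scale (SE 0.170, limma adjusted p = 1.08e-06), as were COL3A1 at -2.17, EGLN3 at -1.81, the receptor subunit GABRE at -1.67 and CPA4 at -1.60. The aldo-keto reductases AKR1C1 and AKR1C3 were higher in sh3293 by 1.64 (SE 0.142) and 1.45, the kinase TNIK by 1.39, the cystine transporter SLC7A11 by 1.34 and GLT8D2 by 1.32. AKR1C genes are close paralogs, so their values may share signal and are uncertain. Of 33297 probe sets 350 were higher and 502 lower in sh3293, and of genes 266 were higher and 342 lower.

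Of 18 ERBB receptors and ligands 2 were higher and 2 lower in sh3293, with EGF higher by 1.26 (SE 0.144). In other lists STC2 was at -1.41, FN1 at -1.26, ACTA2 at -0.76 and IER3 at -0.91, while MYB was higher by 0.74 and CCND1, a cyclin of the start of the cell cycle, by 0.53. Mitosis was the 1 list called, with a median of -0.10 and 2 of 25 members lower, among them CENPF by -0.55 (camera adjusted p = 0.0129, adjusted p = 0.760 with an estimated correlation). Interferon response was not called (camera adjusted p = 0.305), with IFI6 at -0.62. Median and mean differed in sign for ERK pathway output and oestrogen response, neither of them called.

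The total of 852 probe sets between the hairpin lines became 228 and 232 without sh2608 replicates 1 and 2 and 474 without sh3293 replicate 2. The mitosis list lost its call without sh2608 replicate 2 (camera adjusted p = 0.143) or sh3293 replicate 2 (0.0846) and by fry (0.0856), and GLT8D2 without sh2608 replicate 1 (limma adjusted p = 0.0712).

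The comparison of shEGFP with WT gave the background of a hairpin against a gene that is not human. AKR1C3 was lower by -1.51 on the log2 scale (SE 0.153, limma adjusted p = 0.00039), AKR1C2 by -1.24, the adrenergic receptor ADRA2C by -1.23, AKR1C1 by -1.21 and ART4 by -1.17. The lectin CLEC3A rose by 1.53 (SE 0.226), the glycoprotein hormone subunit CGA by 1.35, the immune checkpoint protein VTCN1 by 1.21, and EHMT1-IT1 and LOC389834 by 1.10 each. Of 33297 probe sets 649 were higher and 245 lower, while of genes 105 were higher and 205 lower. Of the probe sets, 435 of those higher and 19 of those lower were unlisted. In the ERBB list 0 of 18 members were called by limma, with 2 lower and 0 higher at an unadjusted p under 0.05.

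Of the 23 lists 9 were called in shEGFP versus WT by camera and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. Mitosis was higher with 4 of 25 members called (camera adjusted p = 2.06e-09, adjusted p = 0.294 with an estimated correlation). Oestrogen response was lower with 6 of 27 called (camera adjusted p = 2.17e-07, adjusted p = 0.294 with an estimated correlation), among them the cyclin CCND1 at -0.49. Cholesterol synthesis with 2 of 15, hypoxia and glycolysis with 3 of 19, DNA replication with 1 of 24 and luminal markers with 3 of 20 were lower (camera adjusted p from 5.49e-07 to 0.000617, adjusted p from 0.294 to 0.498 with an estimated correlation). ERK pathway output with 4 of 22, interferon response with 1 of 29, and lysosome and autophagy with 0 of 15 called by limma and 4 lower at an unadjusted p under 0.05 completed the lower lists (camera adjusted p from 0.00566 to 0.0124, adjusted p from 0.294 to 0.342 with an estimated correlation). PRLR rose by 0.45. The FOXO, basal, mesenchymal, mammary secretory, NF-kB and endothelial lists had negative medians and means with a camera direction of up, none of them called. Camera sets a list against the other genes, and the median change over all 18417 genes was -0.06 in shEGFP versus WT.

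The total of 894 probe sets for shEGFP versus WT became 324 and 397 without WT replicates 1 and 2, 350 and 234 without shEGFP replicates 1 and 2, and 0 in limma without the variance trend, where 4765 had an unadjusted p under 0.05. Lost calls were those of CLEC3A without shEGFP replicate 2 (limma adjusted p = 0.0522), AKR1C2 without WT replicate 2 (0.0758) or shEGFP replicate 2 (0.0982), ADRA2C without WT replicate 1 (0.0639) or shEGFP replicate 2 (0.0652), EHMT1-IT1 without any 1 of these 4 arrays (0.0669 to 0.193), the ERK list without WT replicate 2 (0.0994), the interferon list without WT replicate 1 (0.0616) and the luminal list by fry (0.0512).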

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

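The tests of a response to any hairpin, of fibroblasts, of a single outlying array and of one factor for a whole array were chosen only after the result was seen.

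In CTNND2 the 4 ERBB3 shRNA arrays held 1 value far from the others, sh3293 replicate 1, where the gap to the nearest array was 0.832 of the whole range; 48 groups of 4 arrays were examined, and chance sets apart about 1 in 20 such groups. Genes named for the comparisons with controls that differed between the hairpin lines (sh3293 minus sh2608, log2, limma) were PGM2L1 at 1.01, SEMA3D at 0.86, CA8 at 0.85 and AKR1C3 at 1.45, higher in sh3293. Lower in sh3293 were TGFB2 at -1.25, PSCA at -1.04, NPNT at -0.85, PLCE1 at -1.20, GRIK4 at -0.72, KCNMA1 at -0.72, CCL2 at -3.13, COL3A1 at -2.17, STC2 at -1.41, CPA4 at -1.60 and the mitosis list with a median of -0.10, whose call was lost with an estimated correlation (camera adjusted p = 0.760), by fry (0.0856) and without sh2608 replicate 2 (0.143) or sh3293 replicate 2 (0.0846).

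The number of probe sets called in ERBB3 shRNA versus control was 478, and of the 35 splits of the 8 arrays into 4 and 4 only the real 1 gave as many, with 33 in the highest other. The arrays of a line are not exchangeable, and the 3 splits that keep lines whole, where the highest other gave 27, are too few for a share under 0.05. In the other splits the correlation of a line's arrays was estimated on 3000 probe sets, with which the real split gave 503; without the block it gave 821, against 152 in the highest other.

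Of 29 interferon response genes 16 were higher in sh2608 and 17 in sh3293, with a list mean change of 0.62 in ERBB3 shRNA versus control and a gap of at least 0.43 between any hairpin and any control array. With an estimated correlation the list was not called (camera adjusted p = 0.0504 in sh2608, 0.100 in sh3293 and 0.0545 in ERBB3 shRNA versus control). A response that any hairpin would give is argued against, since in the list mean a shEGFP array minus a WT array gave -0.15 at the highest. This rests on a single control hairpin line. For infection and selection it holds only if WT cells were neither infected nor selected, which the labels do not settle. A shift shared by probe sets of that brightness is argued against too: the list median of 0.58 lay at percentile 100 of 10000 random lists matched on mean level, whose highest median was 0.18. A response to the hairpins' sequences, to the amount of virus, or to the loss of ERBB3 stays open and was not tested; it may be any of these.

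Genes that differ between sh3293 and sh2608 numbered 608. A deeper knockdown of ERBB3 in 1 of the lines is argued against as the whole cause, since 231 genes changed more in sh2608 and 377 more in sh3293, so that the smaller set held 38.0%. A fibroblast mixture in sh2608 that raised most markers as much as COL3A1 is argued against. The 20 other markers of that list had a median change of 0.0304 (95% interval -0.07 to 0.22) against 2.26 for COL3A1. VIM at 0.41, SPARC at -0.04, COL1A1 at -0.15 and COL1A2 at -0.26, named after their values were seen, were not called. A small mixture could raise only some markers, which a median over the list cannot decide. LUM at 1.34 and FN1 at 0.88 were called higher, as was the list (camera adjusted p = 0.0336, but 0.204 with an estimated correlation, 0.0704 with shEGFP as the only control, 0.0655 without WT replicate 1 and 0.160 without sh2608 replicate 1). A small mixture thus stays open for COL3A1, LUM and FN1. Effects of each hairpin on other transcripts and differences between lines that arose by selection stay open and were not tested.

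Unlisted probe sets were higher in shEGFP than in WT, with 435 of 12083 called higher against 1.01% of listed probe sets. A single outlying array is argued against: with any 1 of the 4 arrays left out the share of unlisted probe sets called higher was at least 4.41 times that of listed ones, with 215 and 254 calls without WT replicates 1 and 2 and 253 and 138 without shEGFP replicates 1 and 2. Over the 3745 brighter unlisted probe sets both WT arrays had lower medians than the 6 others, at -0.08 and -0.03, although the gap to the nearest shEGFP array, 0.0282, was below the largest difference of 0.0556 between arrays of 1 of these lines. One factor for a whole array is not decided by the median changes of 0.0574 in brighter unlisted and -0.0505 in brighter listed probe sets, since all arrays had been brought to nearly 1 distribution, where such a factor is lost and a rise of some probe sets forces a fall of others. What these probe sets measure, a fall of listed ones that the shared distribution of the values turned into their rise, and an effect of the control hairpin, infection or selection stay open and were not tested.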

How the results depend on the processing

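The tests restricted to probe sets with 1 gene symbol, without repeats of identical probe sets, of lists with WT as the only control and of lists without ERBB3 were chosen after seeing the data, and all other alternatives were planned. Over the alternatives run, 0 of 9290 values of named genes reversed in limma (8190 kept their side of the threshold, 1036 lost a call, 64 gained one), and of 1748 values of single lists 60 lost a call, 35 gained one and 0 reversed in camera or fry. Several alternatives alter only the spread or the threshold and could not reverse a gene. Lists counted as reversed only if called both ways. In ERBB3 shRNA versus control the uncalled FOXO, mammary secretory and hypoxia lists had opposite directions in camera and fry. The level of ERBB3 kept its direction and its call in all alternatives, with -1.87 to -1.82 in ERBB3 shRNA versus control, -1.82 to -1.75 in sh2608 and -1.92 to -1.88 in sh3293 when 1 array was left out.

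Called probe sets moved by more than 1.5 times as follows. Without the variance trend, 151 were past the threshold in ERBB3 shRNA versus control, 394 in sh2608, 1107 in sh3293, 153 between the hairpin lines and 0 in shEGFP versus WT by limma, where 4765 had an unadjusted p under 0.05. The cause was not tested. With a 2-fold minimum the counts were 86, 114, 127, 108 and 56, and 52 for the 700 shared by the hairpin lines, which follows from the stricter rule. ERBB3 shRNA versus control gave 821 without the line as a block and 2970 with a mean per line, where the spread between lines no longer enters, 741 with shEGFP as the only control and 766 among probe sets with 1 symbol. In sh3293 versus control WT as the only control gave 2059. With only the arrays of the lines compared, 350 were called between the hairpin lines and 580 in shEGFP versus WT, where the spread rests on fewer arrays. Among probe sets with 1 symbol shEGFP versus WT gave 435, 159 higher and 276 lower, so 36.6% were higher in place of 72.6%. Shared calls were 377 with sh2608 versus WT and sh3293 versus shEGFP, and 409 with the opposite assignment. For values with no stated reason the cause was not tested.

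Leaving out 1 array gave 269 to 455 calls in ERBB3 shRNA versus control, 309 to 1677 in sh2608, 1489 to 2652 in sh3293, 228 to 675 between the hairpin lines, 234 to 1093 in shEGFP versus WT and 199 to 618 shared; a lone array of a line was assumed to vary like the other lines. Lists called were 4 to 6, 6 to 8, 4 to 5, 0 to 2 and 8 to 10 in the same order of comparisons, the 0 by camera. With an estimated correlation camera called 0 lists in every comparison, against 4, 4, 3, 0 and 2 at an unadjusted p under 0.05. By fry 10 lists were called in ERBB3 shRNA versus control and 3 between the hairpin lines, and with shEGFP as the only control 3 in ERBB3 shRNA versus control and 3 in sh3293; with WT as the only control 9 were called in ERBB3 shRNA versus control. The cause was not tested.

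Deviations of same-numbered arrays correlated between -0.0902 and 0.147 over the 6 pairs of lines, so any pairing by replicate number was weak across all probe sets. It is not excluded for some of them. In every line the median of the brighter unlisted probe sets was higher in replicate 2 than in replicate 1, and that of listed ones lower. With the replicate number as a block, calls numbered 369, 1739, 3820, 1107 and 1196, against 478, 1366, 3197, 852 and 894 without it. No detection call or background level was used, so dim genes are limited by their signal: leaving out the dimmest 25% or the dimmer 50% moved no count of probe sets by more than 1.5 times.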

Other observations

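The correlation of the hairpin changes with those of the control hairpin was a test written down before its result was seen, and no test of this part was chosen afterwards.

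AKR1C3 and AKR1C1 stood apart in 2 comparisons: they were lower in shEGFP versus WT, at -1.51 and -1.21, and higher in sh3293 versus sh2608, at 1.45 and 1.64. The intensity of AKR1C3 was 173 ± 6.34 (SD, n = 2) in WT, 50.4 ± 4.31 (SD, n = 2) in shEGFP, 120 ± 6.62 (SD, n = 2) in sh2608 and 355 ± 8.07 (SD, n = 2) in sh3293. Close paralogs share sequence, so the values of AKR1C genes are uncertain. The prolactin receptor PRLR rose by 0.45 in shEGFP versus WT and fell by 0.81 in ERBB3 shRNA versus control.

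The hypothesis that the hairpin lines repeat the changes of the control hairpin was tested across genes, which are not independent replicates. The changes of ERBB3 shRNA versus control and shEGFP versus WT correlated at -0.149, against -0.03 to 0.02 in 100 simulations with no effect. WT enters both comparisons with the same sign and shEGFP with opposite signs, so a value below 0 arises where changes of the shEGFP line alone outweigh those of WT alone and those shared with the hairpin lines. A smaller shared part stays open, so the bound set before the result was seen does not decide it. For the same reason the genes called in both comparisons do not decide it: 2 rose in both, 2 fell in both, 9 rose in shEGFP and fell with ERBB3 shRNA, and 27 fell in shEGFP and rose with ERBB3 shRNA.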
